A study of Macaca fascicularis with 25 samples.

How the data were processed

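Nasal scrapes were taken with a curette from sedated cynomolgus macaques, blind and probably from the lower turbinate, per the series' design text, and all samples are labelled as treated with poly I:C. Total RNA (100 ng) was amplified and labelled with biotin by a 3' IVT kit for Affymetrix arrays, per the labels' protocols. The authors deposited log2 expression values made with RMA, per the submitters' processing notes; the RMA version is not given in the sources used here. RMA corrects the background, normalizes between arrays by quantiles and summarises probes, so that a change in the total amount of RNA is not seen. The probesets are those of a human array read with macaque RNA, so that a probe whose sequence differs in macaque reads low. The table holds 20445 probesets on 25 arrays, part of the array's probesets, and no filter is stated. Values ran from 2.11 to 13.2, and array medians from 5.86 to 5.99. No detection calls were used here.

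Probesets were named from the platform annotation: 18266 have 1 gene symbol, 449 several and 1730 none, giving 11396 genes, of which 4432 have several probesets. A gene with several probesets was represented by the one with the highest mean over all arrays, and disagreement of the others is stated for named genes.

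Changes over time were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values of all 25 arrays, with animal as a fixed block plus time. The response of each sensitization group and the difference of responses were fitted with animal plus time within group. Sensitized and naive levels, at 0 h and as the mean over the 4 times, were fitted on 8 group means with animal as a random block (duplicateCorrelation, consensus correlation 0.0515). The block follows from the labels, which name the animal of each array; residuals of arrays of the same animal correlated at 0.0657 on average and of different animals at -0.0534. Correlations between arrays ran from 0.789 to 0.977, with 0 identical pairs. Adjusted p-values are limma's or camera's with Benjamini-Hochberg adjustment, all two-sided, and the threshold is 0.05. Beside a log2 change the text gives its standard error.

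Before the data were examined, 30 gene lists were fixed: 14 functional, 15 of cell type markers and 1 of sex-linked genes for identity. Of the first 29, 28 were tested, with at least 3 measured members each, by camera with a preset correlation of 0.01. The list of 10 interferon genes (such as IFNB1) had 0 measured members and was not tested; MX1, CXCL10 and the olfactory marker OMP were not analysed here. Marker lists describe the level of markers in bulk RNA, not counts of cells, and some genes are in more than 1 list (LYZ, FCER1A and ALOX15, for example). Camera with an estimated correlation was an alternative, and in no comparison did a call of camera hold with it. For the levels of sensitized and naive animals this alternative did not use animal as a block. It thus treated the arrays of an animal as independent there. fry, with and without direction, tests whether the members of a list change, without comparing them with other genes. Where members were adjusted over the list alone, no correction was made across the 28 lists or across comparisons. Some members can thus pass that way by chance. A list's score per animal is the mean change of its members from that animal's 0 h array, and sensitized and naive scores were compared by exact two-sided permutation tests.

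Genes were named by a rule fixed in advance: for each time against 0 h, the 8 highest and 8 lowest changes past the threshold with the same sign in every animal, plus up to 2 members of each list past the threshold; for other comparisons, the 5 highest and lowest past the threshold or, where fewer than 3 passed, the 5 with the smallest p. The genes ISG15, IFIT1, IL6, CXCL8, FOXJ1, MUC5AC and KRT5 (over time) and CLCA1, POSTN, ALOX15, CCL26, FCER1A, IL13 and CPA3 (between groups) were fixed as genes that might be given whether or not they passed; the report gives them at each time against 0 h and for each difference between the groups. Other list members are examples chosen after their values were seen, as were CDH11 in naive animals and the INSR probeset from 6 h to 24 h.

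The steps were tested on simulated data with known changes. Of genes given 1 log2, the test found 79% at 6 h, 87% at 24 h and 75% at 72 h. For sensitized against naive it found 57% at 0 h and 93% over all times. Over all times 36 unchanged probesets were called beside 93 and 99 changed ones, against 8 to 12 unchanged in these other comparisons. A list shifted by 0.5 was called and 0 of 27 others were. Simulated genes varied independently, while real list members moved together (mean correlation 0.279 for interferon-stimulated genes). The list result thus says nothing about false list calls in the real data. The number of arrays limits the precision: the median standard error of a change was 0.16 log2 at 6 h, 0.14 at 24 h and 0.15 at 72 h. Alternatives were no block or a random block, repeated quantile normalization, median centring, removal of the 40% dimmest probesets, array weights, a trended and robust prior, 1 probeset or the mean of probesets per gene, a 2-fold minimum, subsets of animals and arrays, and leaving out each animal in turn.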

Results

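Gene expression was measured on 25 Affymetrix arrays of nasal scrapes from 7 cynomolgus macaques labelled as treated with poly I:C, a synthetic double-stranded RNA that cells sense as they sense viral RNA. Of the animals, 4 had been sensitized to the roundworm Ascaris suum (AS1 to AS4) and 3 were naive (NV1, NV2 and NV4). Each animal was scraped repeatedly, giving 4 sensitized and 3 naive arrays at 0 h, 3 and 2 at 6 h, 4 and 3 at 24 h, and 3 and 3 at 72 h. A change from 0 h could be followed in 5 animals at 6 h, 7 at 24 h and 6 at 72 h, and 4 animals had all times. The series' design text calls 0 h the baseline, while the labels give poly I:C for these arrays as well and the time of dosing is not stated in them. No arm without poly I:C was analysed here, so the treatment, the time of sampling and the earlier scrapes cannot be told apart in any comparison with 0 h. Array medians lay between 5.86 and 5.99 on the log2 scale, and the number of arrays limits the precision.

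The response of the nasal mucosa at 6 h was addressed first. RNF19A, an E3 ubiquitin ligase, rose by 1.09 ± 0.13 log2 (SE, 5 animals, 2.13-fold, adjusted p = 0.00224), and NOCT, a rhythmically expressed regulator of metabolic mRNAs, by 1.28 ± 0.24 (adjusted p = 0.0339), each in 5 of 5 animals. The stress-inducible gene GADD45G (0.94 ± 0.18), the decoy receptor TNFRSF10D (0.93 ± 0.16), the insulin receptor INSR (0.84 ± 0.15) and the MAP kinase phosphatase DUSP4 (0.73 ± 0.14) also rose in 5 of 5 animals, with adjusted p between 0.0223 and 0.0492. SLITRK6, a neuronal and epithelial transmembrane protein, fell by 1.60 log2 (SE 0.25, 3.03-fold, adjusted p = 0.0151) in 5 of 5 animals. RNF152 (-1.33 ± 0.22), the homeobox gene OTX2 (-1.26 ± 0.22), the guanylate cyclase subunit GUCY1A1 (-1.11 ± 0.21), the guanine nucleotide exchange factor VAV3 (-1.08 ± 0.16), the stress gene SESN3 (-1.01 ± 0.17), the kinase NUAK1 (-0.91 ± 0.16) and the co-receptor RGMB (-0.91 ± 0.12) fell in 5 of 5 animals, with adjusted p of 0.0353 or lower. By limma, 11 probesets were higher and 18 lower than at 0 h, naming 8 and 12 genes. Applying quantile normalization again gave 21 higher and 19 lower, array weights gave 73 higher and 86 lower, and 0 passed in the 4 animals with all times. The count was 1 without AS4, 4 without NV2, 7 without AS3, 9 without NV4 and 14 without AS2. Without animal as a block NOCT, TNFRSF10D, RNF152, GUCY1A1 and VAV3 lost their calls. Of the named genes, RNF19A alone kept its call without each of the 7 animals in turn. The other RNF19A probeset rose too but did not pass. The other probesets of DUSP4, OTX2, RNF152 and GUCY1A1 also had the same sign without passing.

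Antiviral genes did not shift as a group at 6 h. The mean change of 33 measured interferon-stimulated genes was 0.05 log2, with 17 positive (camera, adjusted p = 0.638). Animals went opposite ways: the list's mean was higher in 3 of 5 and ran from -0.382 in NV4 to 0.779 in AS4. IFIT1 was at -2.565 and 3.082 in these animals. ISG15, a ubiquitin-like antiviral modifier, changed by 0.07 ± 0.14 (adjusted p = 0.848) and IFIT1, which binds viral RNA, by 0.22 ± 0.65 (adjusted p = 0.897), each positive in 4 of 5 animals. IFIT1 was at -0.41 and ISG15 at -0.04 at the lowest when 1 animal was left out, so neither had a settled direction. The 21 genes of viral RNA sensing and interferon signalling averaged 0.12 (adjusted p = 0.128). SOCS1, a member that restrains cytokine signalling, rose on 1 of its 3 probesets (0.76 ± 0.12, adjusted p = 0.0151), while its brightest probeset was at 0.04 ± 0.10 (adjusted p = 0.893).

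Early-response and inflammatory genes stood above the rest of the array at 6 h. All 11 measured immediate early and heat shock genes, the first transcripts a stimulated or stressed cell makes, were positive, with a mean of 1.13 log2 (camera, adjusted p = 2.58e-09, adjusted p = 0.59 with an estimated correlation). Of 20 fixed members 11 were measured, and HSPH1 was the only heat shock gene among them, so the list speaks for immediate early genes. The list's mean was higher in 5 of 5 animals. Among them EGR3 was at 2.63 ± 0.71, FOS at 1.75 ± 0.54 and ZFP36 at 1.28 ± 0.37. Of the list 8 members passed when adjusted over the list alone against 0 over all genes. Of 25 acute inflammatory cytokines and NF-kB targets 24 were positive, with a mean of 0.86 (adjusted p = 2.58e-09, adjusted p = 0.59 with an estimated correlation), and the list was higher in 5 of 5 animals. PTX3, a soluble pattern receptor, was at 2.58 ± 0.81, the neutrophil chemokine CXCL8 at 2.12 ± 0.52 (adjusted p = 0.116), IL1B at 1.92 ± 0.60, PTGS2 at 1.88 ± 0.60 and IL6 at 1.47 ± 0.45 (adjusted p = 0.205), each positive in 5 of 5 animals. These 5 passed when adjusted over the list alone and 0 passed over all genes.

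Markers of the cells in the scrape moved as well at 6 h. Stromal and endothelial markers averaged -0.76 log2, with 12 of 15 negative (adjusted p = 0.00108, adjusted p = 0.59 with an estimated correlation) and the list lower in 5 of 5 animals. Of the members 5 fell when adjusted over the list alone and 0 over all genes, among them the collagen COL3A1 (-2.01 ± 0.66) and the fibroblast receptor PDGFRA (-1.71 ± 0.38). In a split of the list chosen after the changed genes were seen, its 8 fibroblast markers averaged -1.373, with 8 lower. Its 7 vessel and smooth muscle markers averaged -0.058 (interval -0.417 to 0.301), with 3 higher and 4 lower. A fall of endothelial markers was thus not shown at 6 h. All 17 cell division genes were negative, with a mean of -0.75 (adjusted p = 3.59e-05, adjusted p = 0.59 with an estimated correlation), lower in 4 of 5 animals. Basal epithelial (-0.54, adjusted p = 0.0256), squamous (-0.54, adjusted p = 0.0394) and mast cell and basophil markers (-0.42, adjusted p = 0.0415) were lower, and ciliated (0.41, adjusted p = 0.00319), secretory and goblet (0.29, adjusted p = 0.00142), neutrophil (0.50, adjusted p = 0.00118) and B and plasma cell markers (0.18, adjusted p = 0.00422) higher. None of these 7 held with an estimated correlation (adjusted p = 0.615 for squamous markers and adjusted p = 0.59 for the others). Leaving out 1 animal ended the call for ciliated markers (AS1 or NV1), neutrophils (AS4), B and plasma cells (NV2), basal cells (AS1, AS3 or NV1), squamous cells (AS1, AS3, AS4 or NV1) and mast cells (AS1, AS2, AS3, AS4 or NV1). KRT5, a basal keratin, was at -1.08 ± 0.65 (adjusted p = 0.464, 4 of 5 animals), the ciliogenesis factor FOXJ1 at 0.39 ± 0.16 (adjusted p = 0.311, 4 of 5) and the mucin MUC5AC at 0.65 ± 0.32 (adjusted p = 0.376, 4 of 5).

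**Figure D1:**
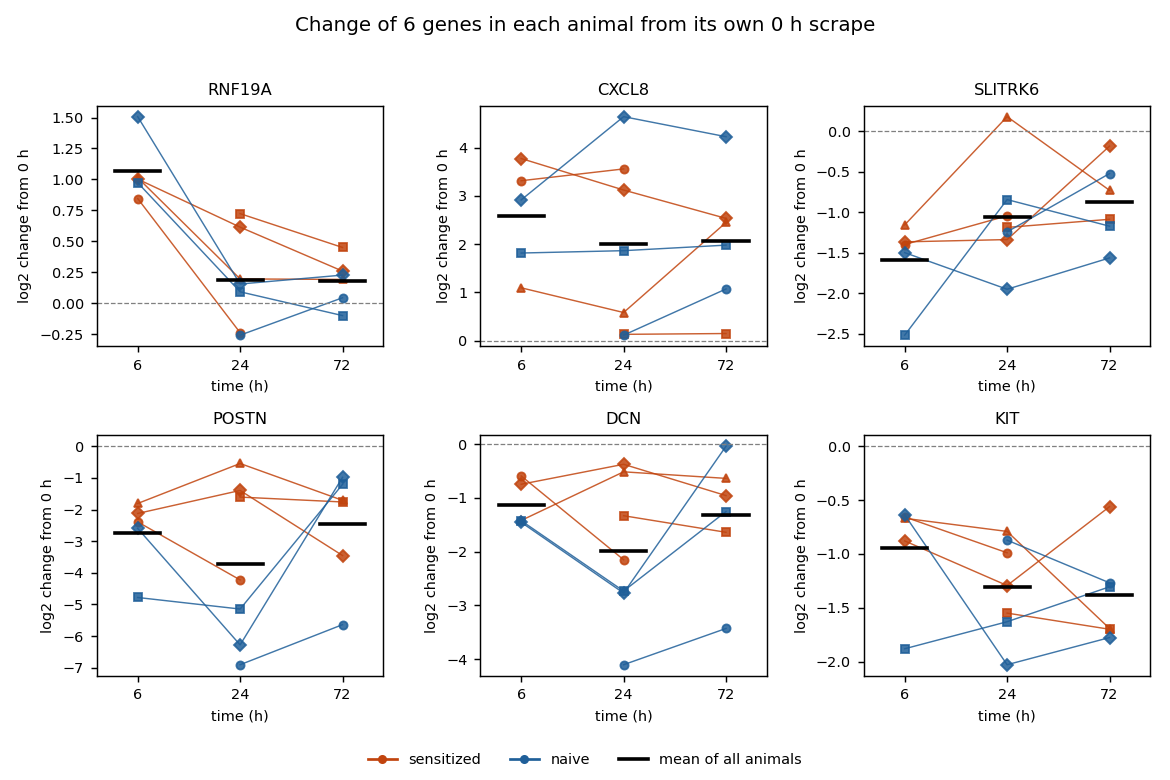
Log2 change from 0 h (vertical axis) of RNF19A, CXCL8, SLITRK6, POSTN, DCN and KIT at 6, 24 and 72 h, 1 point per animal (orange sensitized, blue naive, circle, square, triangle and diamond for animals 1 to 4), with a black bar at the mean of the animals, which is not the fitted value where arrays are missing. RNF19A lies above 0 in 5 of 5 animals at 6 h, and POSTN, DCN and KIT lie below 0 in 7 of 7 animals at 24 h.

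At 24 h the genes past the threshold were lower than at 0 h. POSTN, a matrix protein secreted by fibroblasts and by epithelium exposed to IL-13, fell by 3.73 log2 (SE 0.74, 7 animals, 13.3-fold, adjusted p = 0.0493). A second POSTN probeset fell by 2.67 (SE 0.45, adjusted p = 0.0302). The collagen-binding proteoglycan DCN fell by 2.0 (SE 0.39, 3.99-fold, adjusted p = 0.0456). KIT, the stem cell factor receptor of mast cells, fell by 1.31 (SE 0.20, 2.47-fold, adjusted p = 0.0178), and the complement protease C1S by 0.82 (SE 0.12, adjusted p = 0.0178). The Wnt and agrin receptor LRP4 (-1.14 ± 0.21), the mesenchymal cadherin CDH11 (-1.12 ± 0.20), the heme-binding HEBP1 (-1.06 ± 0.16), the actin-associated SYNPO (-0.88 ± 0.16) and the death ligand TNFSF10 (-0.79 ± 0.15) fell too, with adjusted p between 0.0178 and 0.0432. Of the other TNFSF10 probesets, 1 of 2 had the opposite sign and 0 passed. The other C1S probeset fell too without passing. Each of these 9 genes was lower in 7 of 7 animals. By limma 0 probesets were higher and 29 lower, naming 22 genes. At an unadjusted p under 0.05, 619 were higher and 1521 lower, where chance gives 1022 in all. Array weights gave 105 higher and 254 lower, and 0 passed with only the arrays of 0 h and 24 h or in the 4 animals with all times. The count of 29 rested on most animals: it was 0 without AS1, AS2 or NV1, 1 without NV2 or NV4 and 7 without AS4. It was also 0 without the pair of arrays least correlated with the others (NV1 at 24 h and NV4 at 72 h), where POSTN was still at -3.42 (adjusted p = 0.0951) and KIT at -1.38 (adjusted p = 0.0629). Without animal as a block the count was 8, and POSTN, DCN, LRP4, CDH11 and TNFSF10 lost their calls.

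Stromal and endothelial markers averaged -0.93 log2 at 24 h (camera, adjusted p = 1.65e-06, adjusted p = 0.53 with an estimated correlation), lower in 7 of 7 animals. DCN passed over all genes and 7 of the 15 members fell when adjusted over the list alone, among them COL1A1 (-2.89 ± 0.77), COL3A1 (-2.79 ± 0.58), PDGFRA (-1.54 ± 0.34) and the endothelial cadherin CDH5 (-0.49 ± 0.16). In the same split of the list, its 8 fibroblast markers averaged -1.629, with 8 lower. Its 7 vessel and smooth muscle markers, CDH5 among them, averaged -0.135 (interval -0.453 to 0.184), with 3 higher and 4 lower. A fall of endothelial markers as a set was thus not shown at 24 h. Mast cell and basophil markers averaged -0.53 (adjusted p = 0.000589, adjusted p = 0.527 with an estimated correlation) and were lower in 7 of 7 animals. KIT passed over all genes, and KIT, the prostaglandin D synthase HPGDS (-0.85 ± 0.17) and the IgE receptor chain FCER1A (-0.60 ± 0.23) when adjusted over the list alone. The list also moved one way by fry (adjusted p = 0.041). Squamous markers averaged -0.69 (adjusted p = 0.000893, adjusted p = 0.632 with an estimated correlation), lower in 4 of 7 animals, and this call ended without AS1 or NV1. MHC class II genes, which present antigen to helper T cells, averaged -0.27 (adjusted p = 0.0234, adjusted p = 0.604 with an estimated correlation), lower in 5 of 7 animals, and this call ended without AS2, AS3 or NV1.

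Inflammatory and early-response lists stayed above 0 h at 24 h. Acute inflammatory cytokines and NF-kB targets averaged 0.77 log2 with 23 of 25 positive (adjusted p = 1.08e-08, adjusted p = 0.545 with an estimated correlation), higher in 6 of 7 animals. The neutrophil chemokine CXCL3 was at 2.29 ± 0.56, CXCL8 at 2.0 ± 0.46 (adjusted p = 0.084) and IL1B at 1.98 ± 0.53. Of the list 5 members passed when adjusted over the list alone against 0 over all genes. IL6 was at 0.45 ± 0.40 (adjusted p = 0.717) and was positive in 3 of 7 animals, with AS4 at 2.96 and the others between -0.39 and 0.62. Immediate early genes averaged 0.74, 11 of 11 positive (adjusted p = 1.44e-06, adjusted p = 0.53 with an estimated correlation), higher in 5 of 7 animals. Ciliated cell markers averaged 0.54, 21 of 22 positive (adjusted p = 3.25e-06, adjusted p = 0.548 with an estimated correlation), but were higher in only 4 of 7 animals. Neutrophil markers (0.44, adjusted p = 0.000893), wound response genes (0.37, adjusted p = 0.00606) and chemokines (0.63, adjusted p = 0.0203) were higher, with adjusted p = 0.548, adjusted p = 0.548 and adjusted p = 0.545 with an estimated correlation. These calls ended without NV4, without NV4, and without NV2 or NV4. KRT5 was at -0.88 ± 0.58 (adjusted p = 0.621, negative in 3 of 7 animals), FOXJ1 at 0.25 ± 0.14 (adjusted p = 0.564, positive in 5 of 7) and MUC5AC at 0.12 ± 0.28 (adjusted p = 0.919, positive in 4 of 7). The monocyte chemokine CCL2 was at 2.29 ± 0.62, the protease receptor PLAUR at 1.16 ± 0.34 and the matrix protein TNC at -1.38 ± 0.43.

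Interferon-stimulated genes averaged -0.07 log2 at 24 h (adjusted p = 0.278), with ISG15 at -0.08 ± 0.13 and IFIT1 at 0.06 ± 0.58, in that direction in 4 and 3 of 7 animals (adjusted p = 0.873 and adjusted p = 0.982). The list's mean ran from -0.469 in AS2 to 0.471 in AS4. Complement genes did not shift as a list (mean 0.04, adjusted p = 0.834), yet members changed in both directions by fry without direction (adjusted p = 2.29e-05), with C1S and C1R (-0.56 ± 0.14) lower and the anaphylatoxin receptor C5AR1 (0.84 ± 0.27) higher when adjusted over the list alone. Lists without a shift at 24 h were viral RNA sensing (mean 0.07, adjusted p = 0.372), MHC class I (-0.10, adjusted p = 0.343), cell death and inflammasome (0.08, adjusted p = 0.372), type 2 inflammation (-0.22, adjusted p = 0.895), serous gland (-0.25, adjusted p = 0.563), olfactory (mean -0.07 with an upward camera direction, adjusted p = 0.842), T and NK cell (0.04, adjusted p = 0.563) and eosinophil markers (0.22, adjusted p = 0.177). The other lists without a shift were guanylate-binding (0.18, median -0.01, adjusted p = 0.38), cell division (-0.18, adjusted p = 0.563), secretory (-0.004 with an upward camera direction, adjusted p = 0.563), basal (-0.27, adjusted p = 0.343), monocyte (0.33, adjusted p = 0.0769), dendritic cell (0.17, adjusted p = 0.177), B and plasma cell (-0.03, adjusted p = 0.895) and red blood cell markers (0.37, adjusted p = 0.0687). Of type 2 genes, POSTN alone passed, over all genes and adjusted over the list alone.

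**Figure D2:**
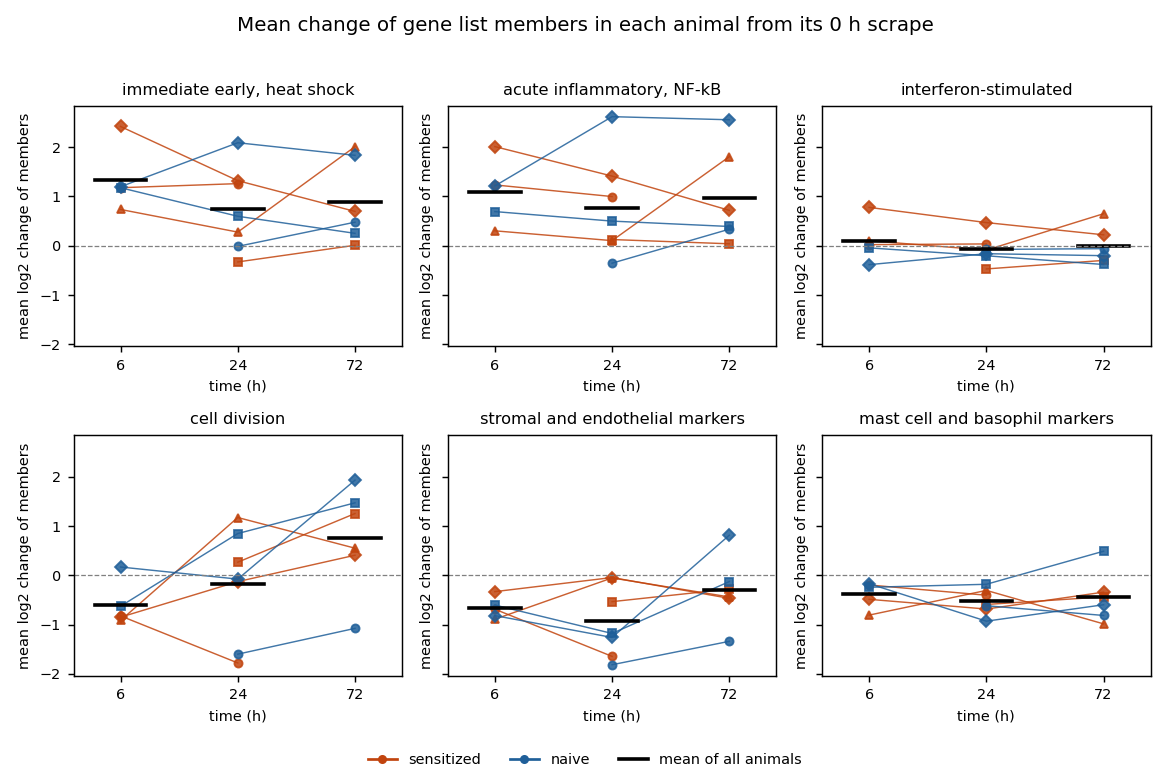
Mean log2 change from 0 h (vertical axis) of the members of 6 gene lists (immediate early, NF-kB, interferon-stimulated, cell division, stromal, mast cell) at 6, 24 and 72 h, 1 point per animal, coloured by sensitization, with a black bar at the mean of the animals. Stromal and mast cell lists lie below 0 in 7 of 7 animals at 24 h, and interferon-stimulated genes lie on both sides of 0 at each time.

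At 72 h inflammatory, chemokine, wound and cell division genes were higher than at 0 h as lists. Acute inflammatory cytokines and NF-kB targets averaged 1.01 log2, 24 of 25 positive (camera, adjusted p = 7.74e-15, adjusted p = 0.321 with an estimated correlation), in 6 of 6 animals, with CXCL3 at 2.68 ± 0.59 and CXCL8 at 2.22 ± 0.48 (each adjusted p = 0.0827). Of its members 6 passed when adjusted over the list alone against 0 over all genes. Cell division genes, which mark proliferating cells, averaged 0.66, 16 of 17 positive (adjusted p = 4.46e-08, adjusted p = 0.321 with an estimated correlation), in 5 of 6 animals. Wound response and extracellular proteolysis genes averaged 0.55 (adjusted p = 3.24e-05, adjusted p = 0.321 with an estimated correlation), with the matrix protein FN1 at 2.13 ± 0.60 and the gelatinase MMP9 at 1.53 ± 0.49. Chemokines averaged 0.91 (adjusted p = 5.29e-05, adjusted p = 0.321 with an estimated correlation), with CCL2 at 2.67 ± 0.65. Immediate early genes (0.91, adjusted p = 2.47e-08) and neutrophil markers (0.54, adjusted p = 0.000129) were higher too, each with adjusted p = 0.321 with an estimated correlation. So were monocyte and macrophage markers (0.51, adjusted p = 0.000971, adjusted p = 0.38 with an estimated correlation), with the scavenger receptor MSR1 at 1.59 ± 0.42.

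Squamous markers averaged -0.80 log2 at 72 h with 19 of 19 negative (adjusted p = 0.000129, adjusted p = 0.438 with an estimated correlation), lower in 4 of 6 animals. Mast cell markers (-0.43, adjusted p = 0.015) were lower in 5 of 6 animals (adjusted p = 0.321 with an estimated correlation). Guanylate-binding and other interferon-gamma-type genes (0.36, adjusted p = 0.00407), dendritic cell markers (0.33, adjusted p = 0.0216) and red blood cell markers (0.48, adjusted p = 0.024) were higher, each with adjusted p = 0.321 with an estimated correlation. Calls ended for mast cells without AS3 or NV1, for guanylate-binding genes without NV4, for dendritic cells without AS3 or NV4, and for red blood cells without AS2, NV1 or NV4. By limma 0 single probesets passed at 72 h (smallest adjusted p = 0.0603), against 2481 at an unadjusted p under 0.05, where 1022 were expected by chance. The count depended on the fit: array weights gave 489 (208 higher, 281 lower), and 1 value per gene 10 (brightest probeset) or 12 (mean). With covariates added after seeing the data it was 25 (stromal marker mean) and 10 (squamous marker mean). KIT alone passed with no block, with a random block or with dim probesets removed, and KIT and C1S without AS4. KIT was at -1.35 ± 0.21 and C1S at -0.69 ± 0.13 (each adjusted p = 0.0603, 6 of 6 animals). Interferon-stimulated genes averaged -0.01 (adjusted p = 0.91, camera direction upward), with ISG15 at -0.09 ± 0.13 (adjusted p = 0.876, 5 of 6 animals) and IFIT1 at -0.08 ± 0.61 (adjusted p = 0.985, 3 of 6). Their list mean ran from -0.379 in NV2 to 0.651 in AS3. IL6 was at 0.62 ± 0.42 (adjusted p = 0.601, 5 of 6), MUC5AC at -0.47 ± 0.30 (adjusted p = 0.571, 4 of 6), KRT5 at -0.40 ± 0.61 (adjusted p = 0.875, 4 of 6) and FOXJ1 at 0.01 ± 0.15 (adjusted p = 0.994, 2 of 6). Of the other MUC5AC probesets 1 of 2 had the opposite sign at 72 h, and MUC5AC ran from -0.70 to -0.09 with 1 animal left out and was at -0.08 without the pair of arrays least correlated with the others.

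Times were also compared directly. From 6 h to 24 h RNF19A fell by 0.91 log2 (SE 0.13, adjusted p = 0.0211) and so did 1 probeset of INSR (-0.81 ± 0.12, adjusted p = 0.0211). The other RNF19A probeset fell too without passing. At an unadjusted p under 0.05 there were 1053, where chance gives 1022, and by limma 2 probesets passed, 1 of each gene. The count was 0 without AS1, AS3, NV2 or NV4, 1 without AS2 and 6 without NV1. Cell division genes were higher as a list, 17 of 17 positive with a mean of 0.56 (adjusted p = 4.54e-06, adjusted p = 0.763 with an estimated correlation). The list's mean was higher in 3 of 5 animals and lower in AS1 and NV4, and 0 members passed when adjusted over the list alone or over all genes. B and plasma cell (-0.21, adjusted p = 0.000169), secretory (-0.30, adjusted p = 0.000606), MHC class II (-0.25, adjusted p = 0.0187), immediate early (-0.39, adjusted p = 0.0187) and serous gland lists (-0.46, adjusted p = 0.0389) were lower. None held with an estimated correlation (adjusted p = 0.578 for B and plasma cells and adjusted p = 0.938 for immediate early genes, adjusted p = 0.763 for the others). From 24 h to 72 h cell division genes averaged 0.85 (adjusted p = 2.3e-17, adjusted p = 0.614 with an estimated correlation). CCNB1 (1.63 ± 0.42) and UBE2C (1.12 ± 0.35), which drive mitosis, passed when adjusted over the list alone against 0 over all genes. Stromal markers averaged 0.59 (adjusted p = 2.09e-06, adjusted p = 0.614 with an estimated correlation) and ciliated markers -0.40 (adjusted p = 9.18e-05, adjusted p = 0.703 with an estimated correlation). Chemokines, guanylate-binding, NF-kB and MHC class II lists were higher by 0.16 to 0.28 and lost with an estimated correlation (adjusted p = 0.703). By limma 0 probesets passed from 24 h to 72 h, with 486 at an unadjusted p under 0.05, fewer than the 1022 that chance gives.

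Within the naive animals, POSTN fell by 6.11 log2 at 24 h (SE 0.83, 69.0-fold, adjusted p = 0.0134), DCN by 3.20 (SE 0.49, 9.20-fold, adjusted p = 0.0343), the extracellular superoxide dismutase SOD3 by 1.40 (SE 0.22, adjusted p = 0.0343) and CDH11, by 1 probeset, by 2.74 (SE 0.43, adjusted p = 0.0343). A second POSTN probeset fell by 4.06 (SE 0.55, adjusted p = 0.0134), and the mean of the POSTN probesets by 5.08. These 4 genes account for the 7 probesets that passed by limma, all lower. The count was 0 with animal as a random block or with no block. It ran from 0 to 41 with 1 animal left out. The call ended without AS2, AS3, AS4 or NV4 for POSTN, without these or NV1 or NV2 for DCN, and without AS1, AS2, AS3, NV1, NV2 or NV4 for SOD3. At 6 h and 72 h 0 probesets passed in naive animals, with 3419 and 2464 at an unadjusted p under 0.05. Chance gives 1022 at each time. Without NV4 260 probesets passed at 6 h, where a single naive array was left and was assumed to vary like the other groups, and without NV1 132 passed at 72 h. POSTN was at -4.33 ± 0.95 at 6 h (adjusted p = 0.13). In sensitized animals 0 probesets passed by limma at 6, 24 and 72 h, with 1281, 627 and 819 at an unadjusted p under 0.05. Chance gives 1022 in each case, so the counts at 24 and 72 h were below it. Array weights gave 16, 25 and 11 there, and 1 and 108 in naive animals at 24 and 72 h. POSTN was at -1.94 ± 0.72 in sensitized animals at 24 h (adjusted p = 1), and the smallest adjusted p at 6 h was that of RNF19A, NUAK1 and the synaptic adhesion gene LRRC4 (adjusted p = 0.169, log2 1.02, -1.12 and 2.11).

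Whether sensitization altered the response was tested as the difference of the changes. At 24 h POSTN was at -1.94 log2 in sensitized and -6.11 in naive animals, a difference of 4.16 ± 1.09 that did not pass (adjusted p = 0.999). The POSTN difference was 2.35 ± 1.24 at 6 h (adjusted p = 0.603) and 0.001 ± 1.14 at 72 h (adjusted p = 1). At 72 h CLCA1, an IL-13-induced goblet cell protein, was at -0.62 and -2.41 (difference 1.79 ± 0.78, adjusted p = 0.998), against differences of -0.36 at 6 h and -0.89 at 24 h. At 6 h IL13 was at -0.16 and 0.42 (difference -0.58 ± 0.22, adjusted p = 0.577), against -0.48 at 24 h and -0.15 at 72 h. ALOX15, CCL26, FCER1A and CPA3 differed by -0.67 to 0.55 over the 3 times, with adjusted p of 0.634 or higher. By limma 0 probesets differed at 6, 24 or 72 h, with 1688, 626 and 716 at an unadjusted p under 0.05. Chance gives 1022 in each case, so the counts at 24 and 72 h were below it. On simulated data the test at 24 h found 22% of genes given a difference of 1 log2 and 84% of those given 2. Stromal markers fell less in sensitized animals at 24 h (difference 0.85, 14 of 15 positive, camera, adjusted p = 0.00917, adjusted p = 0.924 with an estimated correlation), and this ended without NV2. The list's mean per animal was -0.57 ± 0.75 (SD, n = 4) in sensitized and -1.42 ± 0.34 (n = 3) in naive animals (exact two-sided permutation p = 0.143, adjusted p = 1 over 84 tests). Interferon-stimulated genes differed by 0.37 at 6 h (adjusted p = 0.0151, adjusted p = 0.993 with an estimated correlation), which ended without AS4 or NV4. They differed by 0.39 at 72 h (adjusted p = 0.0145, adjusted p = 0.918 with an estimated correlation), which ended without AS3 or NV4. At 6 h squamous markers differed by -1.62 (adjusted p = 1.36e-05) and B and plasma cell markers by -0.34 (adjusted p = 0.0151), both lost with an estimated correlation (adjusted p = 0.993) and ended without NV4 and without NV1 or NV2. At 72 h MHC class II genes differed by -0.54 (adjusted p = 0.00057, adjusted p = 0.918 with an estimated correlation). Of the 84 exact tests of list means 0 reached p below 0.05 unadjusted, but those at 6 h (3 animals against 2) and at 72 h (3 against 3) cannot go below 0.1. For type 2 genes the difference at 24 h had a mean of 0.11, a median of -0.24 and a downward camera direction (adjusted p = 0.344).

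Sensitized and naive animals were then compared in level. Over all times interferon-stimulated genes were higher in sensitized animals, 29 of 33 positive with a mean difference of 0.31 log2 (camera, adjusted p = 1.74e-11, adjusted p = 0.13 with an estimated correlation). IFIT2 (1.24 ± 0.44), the antiviral enzyme RSAD2 (0.74 ± 0.22), DTX3L (0.63 ± 0.13) and the RNA sensor OAS2 (0.61 ± 0.17) were among 10 members higher when adjusted over the list alone, against 0 over all genes. Without regard to direction the list also changed by fry (adjusted p = 0.00867). MHC class I genes were higher by 0.21, 17 of 18 positive (adjusted p = 6.27e-05, adjusted p = 0.13 with an estimated correlation), with the immunoproteasome subunit PSMB8 at 0.66 ± 0.16 and the peptide-trimming ERAP2 at 0.77 ± 0.16. Cell death genes were higher by 0.20, 13 of 13 positive (adjusted p = 0.00203, adjusted p = 0.13 with an estimated correlation). Leaving out any 1 animal ended none of these 3 calls. These lists were not tested on means per animal or with sex as a covariate. For levels, camera with an estimated correlation was run without animal as a block. NV1 and NV2, both naive, differed from the other animals in sex-linked genes (below), so sensitization and sex cannot be fully told apart. At 0 h the mean level of interferon-stimulated genes was 5.80 in AS4 and 6.20 in NV4, so arrays of the groups overlapped. MUC5AC was at 1.13 ± 0.23 and the long noncoding RNA HOTTIP at 1.80 ± 0.38 (each adjusted p = 0.335). MUC5AC (adjusted p = 0.00218) and DTX3L (adjusted p = 0.0372) passed without NV4, and HOTTIP (adjusted p = 0.0372) without AS3. By limma 0 probesets differed, with 1255 at an unadjusted p under 0.05, where chance gives 1022. The count past the threshold was 33 without NV4, 2 without AS2 and 1 without AS3 or AS4.

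Epithelial markers were higher in sensitized animals over all times, basal (0.64, adjusted p = 8.73e-06, adjusted p = 0.293 with an estimated correlation) and squamous (0.67, adjusted p = 1.74e-07, adjusted p = 0.294 with an estimated correlation). Secretory (0.21, adjusted p = 0.00657), neutrophil (0.30, adjusted p = 0.00334), cell division (0.32, adjusted p = 0.0026), wound (0.26, adjusted p = 0.0139) and NF-kB lists (0.24, adjusted p = 0.0309) were higher and were lost with an estimated correlation (adjusted p between 0.518 and 0.724). Calls ended without AS2 or NV4 for secretory, without NV1 for cell division, and without AS4 or NV1 for neutrophil, wound and NF-kB lists. Mast cell markers were lower by 0.27 (mean -0.27, adjusted p = 0.00657, adjusted p = 0.245 with an estimated correlation), as were eosinophil (-0.21, adjusted p = 0.0177, adjusted p = 0.13 with an estimated correlation) and B and plasma cell markers (-0.09, adjusted p = 0.0243, adjusted p = 0.501 with an estimated correlation), calls that ended without NV1 or NV2 and without AS3, NV1 or NV2. Of 10 eosinophil markers only 3 were measured (IL5RA, SIGLEC8 and ALOX15). Of the type 2 genes fixed for this comparison, CLCA1 was at 0.99 ± 0.32 (adjusted p = 0.737), the lipoxygenase ALOX15 at -0.46 ± 0.12 (adjusted p = 0.538), the mast cell protease CPA3 at -0.65 ± 0.29 (adjusted p = 0.801), the eotaxin CCL26 at -0.41 ± 0.17 (adjusted p = 0.801), FCER1A at -0.45 ± 0.19 (adjusted p = 0.801), IL13 at -0.21 ± 0.07 (adjusted p = 0.765) and POSTN at 0.31 ± 0.66 (adjusted p = 0.956).

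At 0 h squamous markers were higher in sensitized animals, 19 of 19 positive with a mean of 1.21 log2 (camera, adjusted p = 6.16e-13, adjusted p = 0.756 with an estimated correlation), a call that no single animal ended. Neutrophil (0.46, adjusted p = 0.000331), cell division (0.36, adjusted p = 0.0129), secretory (0.24, adjusted p = 0.0174) and basal markers (0.63, adjusted p = 0.018) were higher too, each with adjusted p = 0.928 with an estimated correlation. These ended without NV4 for neutrophils, without AS1, NV2 or NV4 for cell division, without AS2, AS3, NV1 or NV4 for secretory, and without AS1, AS3, NV2 or NV4 for basal markers. Interferon-stimulated genes differed by 0.08 at 0 h (adjusted p = 0.106). ALOX15 was at -0.71 ± 0.21, CCL26 at -0.41 ± 0.29, CLCA1 at 0.83 ± 0.56, CPA3 at -0.37 ± 0.52, FCER1A at -0.41 ± 0.34, IL13 at 0.09 ± 0.13 and POSTN at -1.35 ± 1.16 (each adjusted p = 1). By limma 0 probesets differed, with 593 at an unadjusted p under 0.05, fewer than the 1022 that chance gives. The count past the threshold was 13 without NV4. XIST averaged 7.57 and 8.14 in NV1 and NV2 and 3.64 to 3.72 in the other 5 animals. The Y-linked RPS4Y1 averaged 4.61 and 4.44 in NV1 and NV2 and 10.4 to 10.6 in the others, so that sex differs in part with sensitization.

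**Figure D3:**
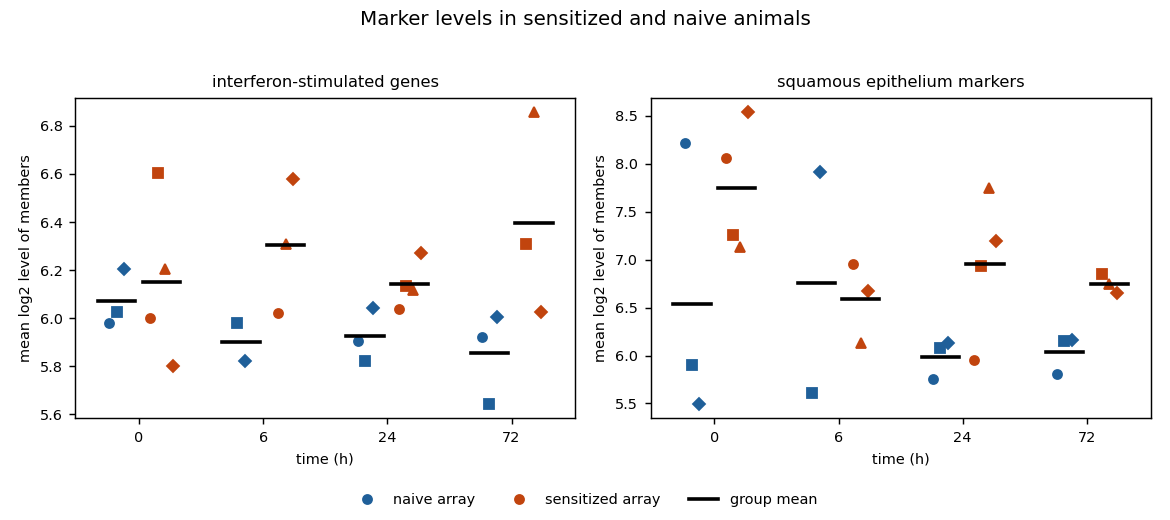
Mean log2 level per array (vertical axis) of the interferon-stimulated and squamous epithelium lists at 0, 6, 24 and 72 h, 1 point per array, naive in blue and sensitized in orange, with a bar at each group's mean. Circle, square, triangle and diamond stand for animals 1 to 4. The mean of squamous markers lies higher in the sensitized group at 0 h, where the difference is 1.21 log2, although the naive animal NV1 lies among the sensitized animals.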

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

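The tests of the 3 patterns weighed here, and the splits with pairs kept from 6 h to 24 h, were chosen after the changed genes had been seen. What each would show was written down before its own result was computed, although DCN, and the change of FKBP5 from 24 h to 72 h, were among the values already seen.

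The first pattern is the fall of stromal genes after 0 h. Repeated quantile normalization gave 36 lower probesets at 24 h, 27 of them among the 29. The deposited values had already been normalized by quantiles, so a further round changes little by construction and cannot decide on array scaling. The median change of all probesets was -0.013, which normalization holds near 0 and so says little. Fibroblast markers averaged -1.629 at 24 h (95% interval -2.508 to -0.75, 8 of 8 lower) and vessel and smooth muscle markers -0.135 (-0.453 to 0.184), while RGS5, a pericyte gene outside that set, was lower. A smaller share of stromal tissue in later scrapes cannot be told apart from lower expression within it, since the vessel interval holds both 0 and a fall, and a response to poly I:C stays open as untested.

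The second pattern is the set of genes changed at 6 h, of which RNF19A and INSR fell again by 24 h. Time of day may contribute: PER2, PER3, DBP and 5 other clock genes changed by -0.666 (95% interval -0.976 to -0.357) relative to BMAL1, NPAS2, CLOCK and CRY1 at 6 h, against -0.086 at 24 h and 0.003 at 72 h, although the first arm alone was also at -0.381 at 72 h. A glucocorticoid response to handling may contribute too: 7 glucocorticoid-induced genes averaged 0.429 at 6 h (0.162 to 0.695, 5 of 7 higher), 0.217 at 24 h and 0.008 at 72 h, with DUSP1 among them and in the immediate early list. Neither test argues against poly I:C, which stays open as untested, since no arm without it was analysed here. Animals scraped at the same clock times without poly I:C would tell them apart.

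The third pattern is that interferon-stimulated genes were not called higher than at 0 h, a time the labels also give as poly I:C treated. Human probes that miss the macaque transcripts are argued against for the list as a whole: its 33 members moved together within groups with a mean correlation of 0.279, above the highest of 1000 random lists matched on level, 0.1. Single probes may still miss their transcript, as the correlation is a mean. Whether the response fell between the times sampled, or did not arise at the scraped site, was not tested.

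Whether chance could be excluded was tested by reassigning arrays to times, or animals to groups, and counting the probesets each split gave, the real split among them. At 24 h 1 of 100 splits, the real one, gave 29 and the highest other gave 0. With times exchanged within animals it was 1 of 64, with 29 against 0. This argues against chance for the count at 24 h without excluding it, as 1 comparison of several. The first set of splits also parts the arrays of an animal, and the count was 0 without AS1, AS2 or NV1. At 6 h these splits do not exclude chance: 5 of 100 gave 29 or more and the highest other 102. That split took 4 arrays of 0 h and 1 of 6 h as the arrays of 6 h, so it is in part the real split turned around. Its count may hold the real change, so it cannot decide between chance and a structure of the samples. With pairs kept at 6 h, 16 splits are too few for a share under 0.05, and the real split gave 29 and the highest other 0 (1 of 16). From 6 h to 24 h 2 of 100 splits gave 2 or more, but these splits part the arrays of an animal freely. The highest other gave 39, from a split that took most arrays of 6 h as arrays of 24 h, and so cannot decide either. With pairs kept, 16 splits are too few for a share under 0.05, and the real split gave 2 and the highest other 0 (1 of 16). In naive animals 10 splits are too few for a share under 0.05. The real and highest other counts were 7 and 81 at 24 h (2 of 10) and 0 and 71 at 72 h (10 of 10), so that at both times another split gave the most.

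Where limma called 0 probesets every split gives at least as many by construction, so that these splits say nothing about chance. They were 100 of 100 splits at 72 h (highest other 8) and from 24 h to 72 h (1), and 32 of 32 with pairs kept at 72 h (0). They were 35 of 35 in sensitized animals at 6, 24 and 72 h (0 each), and also for the differences in response at 24 h and 72 h and the levels at 0 h (1 each). Over all times they were 35 of 35, and the highest other, 39, came from a split that set AS2, NV1 and NV2 against the others. That split put both animals with high XIST together, beside AS2, where XIST was low. Whether its probesets follow sex was not tested, and 15 of the other splits gave calls.

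A single animal lay far from the others in 12 of 128 groups of values, where chance gives about 1 in 20 groups, or 6.4. NV4 gave 5 of them at 6 h, with ciliated markers at -1.864 (others 0.508 to 1.061), basal markers at 1.043 (others -0.961 to -0.472), cell division genes at 0.169 (others -0.915 to -0.626), KRT5 at 1.425 (others -1.531 to -0.853) and RNF19A at 1.507 (others 0.846 to 1.014). At 24 h NV4 was at 0.735 for dendritic cell markers (others -0.118 to 0.204) and at -2.256 for HEBP1 (others -1.12 to -0.614). AS4 was at 2.42 for immediate early genes (others 0.737 to 1.198) and at 0.721 for cell death genes (others -0.045 to 0.135) at 6 h, and at 2.957 for IL6 at 24 h (others -0.392 to 0.622). At 6 h AS1 was at 0.307 for DUSP4 (others 0.678 to 0.82) and NV2 at -2.515 for SLITRK6 (others -1.498 to -1.156).

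The change differed between sensitized and naive animals for 5 lists by camera with a preset correlation, 1 of them at 2 times, and for 0 with an estimated one. At 6 h the difference was 0.373 for interferon-stimulated genes, -1.623 for squamous markers and -0.341 for B and plasma cell markers (each adjusted p = 0.993 with an estimated correlation). At 24 h it was 0.849 for stromal markers (adjusted p = 0.924 with an estimated correlation). At 72 h it was 0.391 for interferon-stimulated and -0.545 for MHC class II genes (each adjusted p = 0.918 with an estimated correlation).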

How the results depend on the processing

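The alternatives without the least correlated arrays and with stromal markers, squamous markers or sex as a covariate were chosen after seeing the data. Of 350 values of named genes recomputed, 291 kept direction and side of the threshold, 44 fell short of it, 3 came to pass it and 12 turned. Of 400 counts recomputed, 273 stayed within 1.5 times and 127 did not. Counts of genes are of probesets past an adjusted p of 0.05 by limma. Median centring and a trended, robust prior moved no count beyond that. Where no construction is named, the cause was not tested. Signal over background limits what dim probesets can show, and no detection calls were used.

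With no replicate block the count was 8 at 24 h, 1 at 72 h (KIT), 1 in sensitized (LRP8) and 0 in naive animals at 24 h; the block changed no other count beyond 1.5 times. Without it 13 calls of named genes were lost, those of POSTN and DCN at 24 h among them. With animal as a random replicate block the count was 9 at 24 h, 1 at 72 h (KIT), 4 from 6 h to 24 h (2 INSR probesets, RNF19A and TRAF3IP3), 1 in sensitized animals at 24 h (LRP8), 1 in naive animals at 6 h (RNF19A) and 0 in naive animals at 24 h. Repeated quantile normalization gave 1 in naive animals at 6 h (RNF19A). With dim probesets removed the counts were 12 at 24 h, 1 at 72 h (KIT) and 4 in naive animals at 24 h (POSTN and 3 of DCN). Array weights, whose estimation stopped before its convergence tolerance, gave 159 at 6 h, 359 at 24 h (105 higher, 254 lower) and 489 at 72 h (208 higher, 281 lower). They gave 1 from 6 h to 24 h (INSR), 16, 25 and 11 in sensitized animals at 6, 24 and 72 h, and 1 (DCN) and 108 in naive animals at 24 and 72 h. The brightest probeset of each gene alone, fewer features by construction, gave 17 at 6 h, 15 at 24 h, 10 at 72 h, 1 from 6 h to 24 h (RNF19A) and 3 in naive animals at 24 h (POSTN, DCN and SOD3). The mean of probesets gave 12 at 72 h, 0 from 6 h to 24 h, 1 in naive animals at 6 h (FITM1), 3 in naive animals at 24 h (the same 3 genes) and 4 shifted lists for the difference at 24 h. A 2-fold minimum left 16 at 6 h, 16 at 24 h and 0 from 6 h to 24 h. The 4 animals with all times, fewer arrays, gave 0 at 6 h, 0 at 24 h and 0 from 6 h to 24 h, and only the arrays of the times compared gave 0 at 24 h. A mean per animal gave 1 gene between groups over all times (SPRR1B).

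Without the 2 arrays least correlated with the others the count was 0 at 24 h, 0 from 6 h to 24 h and 1 between groups over all times (ADRA2A), and 6 lists differed in response at 24 h and 6 at 72 h. The stromal covariate gave 3 at 6 h (RNF19A, VAV3 and RGMB), 0 at 24 h and 25 at 72 h. It is the mean of genes that themselves fell, so its 0 at 24 h says nothing about why they fell. The squamous covariate gave 10 at 24 h and 10 at 72 h, and sex gave 3 between groups over all times (JUN, SPINK1 and MAP3K20).

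With an estimated correlation 0 lists were called in each of the 8 comparisons recomputed. Here fry with direction called 1 at 24 h and 0 in the other 7, and fry without direction 2 at 24 h, 2 at 72 h, 3 between groups over all times and 0 in the other 5.

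Leaving out each animal gave 1 to 38 at 6 h, 0 to 39 at 24 h, 0 to 2 at 72 h, and 0 to 6 from 6 h to 24 h. In naive animals it gave 0 to 260 at 6 h, 0 to 41 at 24 h and 0 to 132 at 72 h. Between groups it gave 0 to 13 at 0 h and 0 to 33 over all times. The 260 came without NV4, which leaves 1 naive array at 6 h, assumed to vary like the other groups. Shifted lists numbered 7 to 13, 7 to 12 and 10 to 13 at 6, 24 and 72 h. They numbered 1 to 8, 0 to 7 and 2 to 11 for the differences in response, and 2 to 9 at 0 h and 7 to 16 over all times between groups. The count stayed at 0 in sensitized animals, from 24 h to 72 h and for the differences.

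Over all arrays none of the values that turned was past the threshold. With 1 animal left out IFIT1 ran from -0.412 to 0.849 at 6 h, from -0.35 to 0.422 at 24 h and from -0.673 to 0.247 at 72 h, and at 72 h it was 0.023 with no replicate block. ISG15 ran from -0.043 to 0.206 at 6 h and from -0.145 to 0.003 at 24 h. At 72 h FOXJ1 ran from -0.155 to 0.095 and KRT5 from -0.889 to 0.165. In naive animals at 24 h ALOX15 ran from -0.215 to 0.113, with 0.045 under repeated quantile normalization, and CCL26 from -0.533 to 0.088. POSTN between groups over all times ran from -0.578 to 0.96.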

Other observations

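Further genes passed at 24 h besides those described above, chosen here after their values were seen. RGS5, a pericyte gene, was lower on 2 probesets (-2.139 and -1.704), and so were the chemokine CXCL14 (-1.544), the matrix-associated CCDC80 (-1.313) and SPON1 (-1.253), the protease inhibitor A2M (-0.783) and the planar polarity gene VANGL2 (-0.706), with adjusted p between 0.0302 and 0.0463 by limma. For RGS5, CXCL14 and SPON1 the brightest probeset of the gene did not pass, and leaving out AS1, AS2 or NV1 ended every call at 24 h.

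Within the naive animals B and plasma cell markers averaged 0.38 at 6 h, 8 of 9 positive (camera, adjusted p = 0.00271, adjusted p = 0.815 with an estimated correlation). CD79A, CD79B and MZB1 rose when adjusted over the list alone, against 0 over all genes. Red blood cell markers averaged 0.89 in naive animals at 72 h, 4 of 4 positive (adjusted p = 0.0133, adjusted p = 0.559 with an estimated correlation). In sensitized animals MHC class II genes averaged -0.39 at 72 h, with 2 of 11 positive (adjusted p = 0.00105, adjusted p = 0.406 with an estimated correlation). For lists within a group, animals were not left out in turn.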
